A study of Escherichia coli str. K-12 substr. MG1655 with 34 samples.

How the data were processed

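Total RNA from 34 cultures of Escherichia coli K-12 MG1655 was measured on spotted Operon oligo arrays, 1 array per culture. The RNA of the culture was labelled with Cy5 and a pool of RNA from all conditions with Cy3 on every array, with no dye swap. The labels give 12 groups: an unstressed control and 11 stress conditions, with 3 arrays each except HCl and NaOH, which have 2. Per the labels, all conditions of a replicate number were grown on 1 day from 1 overnight culture. Groups and replicate numbers were taken from the labels alone. The labels give BC as an abbreviation only, and its doses in different units in different places, so the doses are written here as in the titles.

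Per the file headers, the spot and background intensity values of each channel are raw values quantified in ImaGene from scanned images, with no normalization. In the other table, the authors gave log2 ratios of sample to reference after background subtraction and lowess normalization within each array. The values here were computed from the intensity files with R 4.3.3 and limma 3.58.1, with jsonlite 2.0.0 for reading the labels. The steps were normexp background correction with an offset of 50 on the signal mean, 1 loess curve per array with control spots at weight 0, removal of flagged spots and averaging of the spots of a probe. Of 14688 spots per array, between 11.3% and 37.7% of the gene spots were flagged. A probe was tested if its Cy5 signal lay above the local background by more than 2 background standard deviations on at least 2 arrays. Probes were matched to genes of the MG1655 reference by symbol, locus tag or synonym. Where several probes that passed matched 1 gene (47 genes), only the probe with the highest mean signal was tested. Of 6077 probes, 5242 were tested after both steps, of which 3952 stand for 1 gene each and 1290 matched none and were kept apart.

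Each comparison is a contrast of group means in 1 limma model with a mean per group over all 34 arrays and moderated t tests, and p was adjusted by the Benjamini-Hochberg method within a comparison with a threshold of 0.05. Replicate number was left out of this model, although arrays of 1 number were grown together, and was added as a block in an alternative. The 11 stresses were compared with the control, and the BC doses, the acids, and NaCl and glycerol with each other. In both HCl and NaOH, 2 arrays carry the group, and the spread is shared over all groups. No minimum of measured arrays per group was set for a gene, so a call can rest on 1 array of a group. Where a gene was not well above background in 1 group, the change is given as at least a number of times, computed from Cy5 values quantile-normalized in average intensity, with that group set to the lowest value well above background on each array or to its own value if higher. The 41 gene lists of known regulons and pathways, and the 3 lists paired with each stress, were fixed before the values were read. They were tested with limma camera at a preset correlation between genes of 0.01, adjusted over all lists and the 11 comparisons, and again with the correlation estimated from the residuals. A gene was counted as shared if it passed in the same direction in at least 6 stresses. It was counted as specific to a stress if it passed there alone and also differed from the mean of the other stresses. The shared genes and the list calls were set beside 100 simulations of unchanged groups that share the control arrays. The simulations shuffled the array residuals over the groups without regard to replicate number, while each real group of 3 holds every number once. Simulated counts and shares may therefore differ from those of unchanged groups balanced in replicate number.

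Genes were named by a rule fixed before the values were read. It took the 8 highest and 8 lowest changes per comparison among genes whose arrays did not overlap between groups, the 4 largest changes in each paired list, the 2 largest in any other list that passed, the 12 most shared genes and the 4 most specific genes per stress. From these the text mainly gives genes whose call held under every alternative, a choice made after the values were seen. Of 401 such calls 244 held, from 0 of 5 in BC at 9 ppm and 9 of 37 in NaOH to 38 of 43 at 15 °C and 16 of 16 for NaCl against glycerol. Of the lists, the text gives the paired ones and some of those that passed whichever array was left out, which were 81 of 131. appC in HCl, ymgD and the other calls in BC were named outside this choice. So was the anaerobic respiration list in BC at 7 ppm, whose call ended without 1 array. Of the genes given as not past the threshold, poxB, nhaA, fabA and, in BC at 7 ppm, yebE, acrA and acrB moved by more than 1.5 times when 1 array was left out.

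The pairing by replicate number was checked on the deviations of arrays from their group means. Their mean correlation was 0.12 over 177 pairs with the same number and -0.06 over 352 other pairs. Scan batches, read from the file headers, gave 0.19 over 60 pairs in the same batch and -0.02 over 469 other pairs. Most pairs in the same batch also had the same replicate number, so the 0.19 is not that of scanning alone. Pairs with the same number in other scan batches gave 0.09 over 123 pairs. Where a scan batch held 1 array of each group, the direction of called genes there is not given, since most of them had no overlap between the arrays of the groups, which fixes it. Where no scan batch held both groups, scan batch as a block compares them only through other groups. It then assumes that a batch shifts every group alike, so a count near the main one does not exclude scan batch. Alternatives were no background correction, the signal median, print-tip loess, scaling between arrays, flagged spots kept, no filter on dim probes, only the arrays of the groups compared, replicate number or scan batch as a block, the authors' values, and leaving out each array. The authors' table names no genes, so its lines were matched to the probes by the order of the sorted probe names and used where they correlated with the computed ratios at 0.5 or more. This kept 5391 of 6126 lines, and the median correlation was 0.967. The model was tested on simulated data with 200 changed probes. Between 80.3% and 97% of 4-fold changes and between 14.9% and 41.8% of 2-fold changes were recovered, depending on the comparison. Where fewer genes change, the adjusted threshold is stricter and the shares would be lower. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.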

Results

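Transcript levels were measured in Escherichia coli K-12 MG1655 during exponential growth in the medium labelled TSB under 11 stress conditions and in an unstressed control at 37 °C. The stresses were acetic acid at pH 5.9, HCl at pH 4.75, NaOH at pH 9.6, 5% ethanol, 4.5% NaCl, 15% glycerol, the agent labelled BC at 7 and 9 ppm, EtBr, growth at 46 °C and growth at 15 °C. Each of the 34 arrays compared the RNA of 1 culture, in Cy5, with a pool of RNA from all conditions, in Cy3. HCl and NaOH had 2 arrays each and the other 10 groups had 3. The title of the series asks which responses the stresses share and which are particular to 1 of them, so each stress was compared with the control, related stresses were compared with each other, and the calls were then compared across stresses. Between 51.4% and 89.9% of the probes matched to an MG1655 gene were well above background on an array, with a median of 79.1%. The correlation of log ratios between arrays of 1 group, across probes, ran from 0.276 to 0.812. Values below are log2 changes of the stress against the control with their standard error, and n is the number of arrays in each group. For a gene list, the number of measured members past the threshold over all genes and adjusted over the list alone stands beside the median log2 change and the adjusted p of limma camera.

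**Figure D1:**
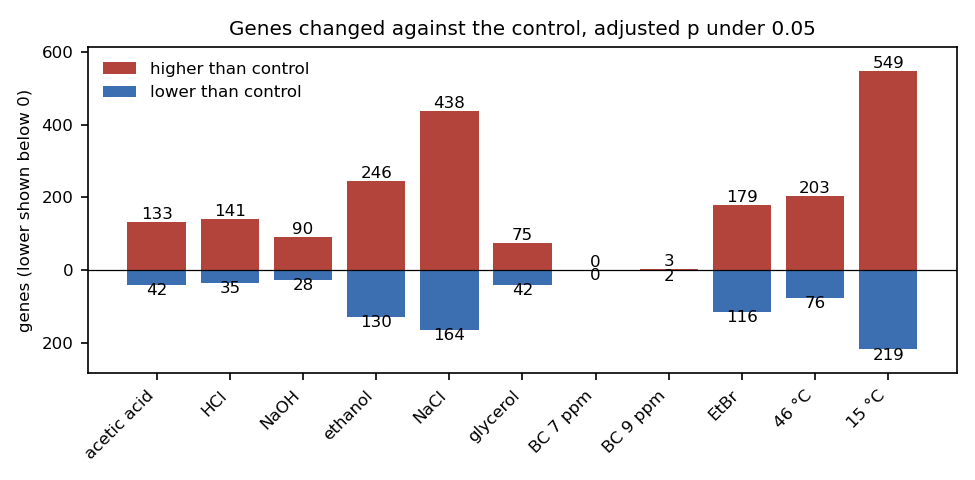
Bars show the number of genes higher (above 0) and lower (below 0) than the control at an adjusted p under 0.05 for each of the 11 stress conditions. Growth at 15 °C gave 549 higher and 219 lower genes, NaCl gave 438 and 164, and BC at 7 ppm gave 0.

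In acetic acid, the acid-resistance genes were among those that rose the most. The periplasmic acid chaperone gene hdeA rose by 4.24 ± 0.53 (n = 3 and 3) and hdeB by 2.66 ± 0.55. The glutamate decarboxylase gene gadB was at least 10.9-fold higher, its antiporter gene gadC at least 8.58-fold, and the activator gene gadE at least 8.9-fold. These 3 genes were not well above background in the control. The membrane lipid gene cfa, for cyclopropane fatty acid synthase, rose by 3.00 ± 0.33. Genes that fell included yghJ, for a surface lipoprotein (-4.12 ± 0.32), the porin gene nmpC (-2.71 ± 0.38), the prophage lipoprotein gene borD (-2.60 ± 0.46) and fadL, for long-chain fatty acid uptake (-2.37 ± 0.28). Every measured member of the glutamate-dependent acid resistance list rose (15 of 15 members higher, 15 adjusted over the list alone, median 2.93, adjusted p = 6.52e-31, adjusted p = 0.00134 with an estimated correlation). The RpoS general stress list was higher (6 of 29 members higher, 12 adjusted over the list alone, median 0.70, adjusted p = 8.16e-07, adjusted p = 0.121 with an estimated correlation), with wrbA, for a quinone oxidoreductase, at 2.31 ± 0.33. The acetate metabolism list did not pass (2 of 9 members higher, 2 adjusted over the list alone, median 0.82, adjusted p = 0.0924, adjusted p = 0.504 with an estimated correlation). Its member poxB, for pyruvate oxidase, had a change of 1.08 ± 0.48, not past the threshold. The TCA cycle list was also higher (2 of 17 members higher, 11 adjusted over the list alone, median 0.76, adjusted p = 2.94e-07, adjusted p = 0.0853 with an estimated correlation). Cysteine synthesis and sulfate assimilation was lower (1 of 16 members higher and 3 lower, 1 and 8 adjusted over the list alone, median -1.11, adjusted p = 1.06e-05, adjusted p = 0.28 with an estimated correlation). Arginine synthesis was lower too (0 of 13 members higher and 2 lower, 1 and 7 adjusted over the list alone, median -0.61, adjusted p = 0.000743, adjusted p = 0.0578 with an estimated correlation, adjusted p = 0.0547 with scan batch as a block). Single biosynthetic genes went both ways: metE, for methionine synthase, rose by 2.00 ± 0.32, while thrA, for aspartokinase, changed by -2.11 ± 0.33 and carB, for carbamoyl phosphate synthetase, by -1.90 ± 0.33. In all, 175 of 3924 genes changed, 133 higher and 42 lower, and 165 of them by at least 2-fold. The count was 112 without acetic acid replicate 1, 99 without replicate 2, 113 without control replicate 1 and 108 without control replicate 2. No scan batch held both groups, and the count was 96 with scan batch as a block and 116 after scaling between arrays.

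HCl gave a related set of changes on 2 arrays against 3 control arrays. The acid shock gene asr rose by 3.66 ± 0.47 (n = 2 and 3) and hdeA by 3.66 ± 0.59, while gadB was at least 8.52-fold, gadC at least 6.26-fold and gadE at least 10.7-fold higher than in the control, where they were not well above background. The stationary-phase genes wrbA and osmY rose by 3.03 ± 0.37 and 3.00 ± 0.45, and cfa by 3.08 ± 0.37. The serine deaminase and transporter genes sdaB and sdaC changed by -3.03 ± 0.56 and -2.86 ± 0.52, yghJ by -4.84 ± 0.36, nmpC by -3.83 ± 0.42 and borD by -3.60 ± 0.51. The glutamate-dependent acid resistance list rose (12 of 15 members higher, 15 adjusted over the list alone, median 2.35, adjusted p = 1.61e-19, adjusted p = 0.013 with an estimated correlation). So did the RpoS general stress list (12 of 29 members higher, 14 adjusted over the list alone, median 1.00, adjusted p = 1.29e-10, adjusted p = 0.0486 with an estimated correlation). The lysine and arginine decarboxylase list did not pass (2 of 10 members higher and 1 lower, 3 and 1 adjusted over the list alone, median 0.60, adjusted p = 0.148, adjusted p = 0.784 with an estimated correlation). The TCA cycle list was higher (8 of 17 members higher, 15 adjusted over the list alone, median 1.22, adjusted p = 2.74e-12, adjusted p = 0.0278 with an estimated correlation), with the aconitase gene acnA at 2.03 ± 0.35. Methionine synthesis was higher (4 of 12 members higher, 5 adjusted over the list alone, median 0.71, adjusted p = 0.00017, adjusted p = 0.0469 with an estimated correlation, adjusted p = 0.052 with scan batch as a block), with metE at 2.75 ± 0.35. The cysteine and sulfate list was lower (0 of 16 members higher and 4 lower, 1 and 10 adjusted over the list alone, median -1.74, adjusted p = 9.41e-08, adjusted p = 0.172 with an estimated correlation). The outer membrane porin list was lower too (3 of 12 members lower, 4 adjusted over the list alone, median -0.22, adjusted p = 0.000422, adjusted p = 0.0842 with an estimated correlation), led by nmpC and by fadL at -2.83 ± 0.32. In all, 176 of 3929 genes changed, 141 higher and 35 lower, 170 of them by at least 2-fold. The count was 64 without HCl replicate 1, 56 without HCl replicate 3, 107 without control replicate 2 and 103 with only the arrays of both groups in the fit. No scan batch held both groups, so scan batch as a block, which gave 170, compares them only through the other groups.

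Acetic acid and HCl were compared directly because both acidify the medium, although to different pH. Only 3 of 3925 genes differed. The acid shock gene asr was lower in acetic acid than in HCl, with a difference of -3.62 ± 0.47, adjusted p = 7.44e-05 (n = 3 and 2), and ydgD, for a putative serine protease, had a difference of -2.05 ± 0.31, adjusted p = 0.000744. The pyruvate transporter gene btsT was higher in acetic acid by 2.67 ± 0.49, adjusted p = 0.0123. In all, 144 genes had an unadjusted p under 0.05 in limma. Only asr stayed past the threshold without HCl replicate 3, and btsT also lost its call without HCl replicate 1 or acetic acid replicate 1. In simulated data for this comparison with 200 changed probes, 80.3% of 4-fold changes and 16.4% of 2-fold changes were recovered. With few changed genes the adjusted threshold is stricter, so these shares overstate what could be found here. A difference of 2-fold or less between the acids was mostly not detectable.

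At pH 9.6, the thiamin synthesis gene thiC rose by 3.94 ± 0.50, thiE by 3.57 ± 0.59, thiG by 3.53 ± 0.44 and thiH by 3.85 ± 0.49 (n = 2 and 3). The phage shock genes pspB and pspC, for membrane stress proteins, rose by 3.11 ± 0.46 and 3.38 ± 0.34, the maltodextrin phosphorylase gene malP by 2.97 ± 0.37, and the ribosome hibernation gene rmf was at least 9.23-fold higher than in the control. The Cpx envelope stress list was higher (6 of 12 members higher, 8 adjusted over the list alone, median 1.04, adjusted p = 3.53e-08, adjusted p = 0.0486 with an estimated correlation). The alkaline pH and sodium-proton antiport list did not pass (0 of 11 members higher and 1 lower, 1 and 2 adjusted over the list alone, median 0.13, adjusted p = 0.804, adjusted p = 0.918 with an estimated correlation). The antiporter gene nhaA had a change of 0.95 ± 0.44, not past the threshold. The ATP synthase list did not pass either (0 of 9 members lower, 0 adjusted over the list alone, median -0.11, adjusted p = 0.84, adjusted p = 0.937 with an estimated correlation). The phage shock list was higher (5 of 7 members higher, 5 adjusted over the list alone, median 2.58, adjusted p = 7.56e-10, adjusted p = 0.0263 with an estimated correlation). The maltose system was higher (3 of 11 members higher, 6 adjusted over the list alone, median 1.11, adjusted p = 7.06e-06, adjusted p = 0.059 with an estimated correlation). Histidine synthesis was higher (2 of 8 members higher, 4 adjusted over the list alone, median 0.99, adjusted p = 1.1e-05, adjusted p = 0.0578 with an estimated correlation). Purine synthesis was also higher (3 of 15 members higher, 7 adjusted over the list alone, median 1.26, adjusted p = 2.45e-05, adjusted p = 0.38 with an estimated correlation). In all, 118 of 3930 genes changed, 90 higher and 28 lower, and 117 by at least 2-fold. Scaling between arrays gave 250 genes, of which 134 were higher and 116 lower, and print-tip loess gave 145, of which 96 were higher and 49 lower. The count was 42 without NaOH replicate 1, 179 without NaOH replicate 3, 56 without control replicate 2, 72 without control replicate 3 and 25, of which 23 were higher, with only the arrays of both groups in the fit. No scan batch held both groups, and scan batch as a block gave 85.

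In 5% ethanol the sugar uptake genes malE and lamB, for the maltose-binding protein and maltoporin, rose by 5.75 ± 0.48 and 4.51 ± 0.42 (n = 3 and 3). The galactitol genes gatC, gatD and gatZ rose by 3.14 ± 0.39, 4.08 ± 0.50 and 3.54 ± 0.48, and the periplasmic chaperone gene spy by 4.90 ± 0.72. norV, for a nitric oxide reductase, was at least 10.4-fold higher. The genes of cytochrome bo oxidase fell, with changes of -3.40 ± 0.39 for cyoA, -3.36 ± 0.44 for cyoB, -2.99 ± 0.36 for cyoC and -3.34 ± 0.44 for cyoE, as did the porin gene ompF (-3.93 ± 0.41), the magnesium transporter gene mgtA (-3.21 ± 0.34) and the gluconate transporter gene gntT (-3.10 ± 0.55). The sigma32 heat shock list was higher (5 of 20 members higher, 5 adjusted over the list alone, median 0.52, adjusted p = 0.00241, adjusted p = 0.466 with an estimated correlation). Its members clpB, dnaK and grpE, for chaperones, rose by 2.49 ± 0.40, 1.41 ± 0.31 and 1.45 ± 0.34. The phage shock list was higher (3 of 7 members higher, 4 adjusted over the list alone, median 1.27, adjusted p = 0.0276, adjusted p = 0.465 with an estimated correlation, adjusted p = 0.0902 without ethanol replicate 1), and without control replicate 3 its adjusted p was 0.086. Its member pspE rose by 1.72 ± 0.38. Fatty acid synthesis was lower (1 of 15 members higher and 4 lower, 1 and 4 adjusted over the list alone, median -0.36, adjusted p = 0.00923, adjusted p = 0.307 with an estimated correlation, adjusted p = 0.061 without ethanol replicate 2, adjusted p = 0.215 with scan batch as a block). Its member fabD, for malonyl transacylase, changed by -1.81 ± 0.30. The maltose system was higher (8 of 11 members higher, 8 adjusted over the list alone, median 1.44, adjusted p = 1.1e-09, adjusted p = 0.0151 with an estimated correlation). The Cpx list was higher (6 of 12 members higher, 9 adjusted over the list alone, median 1.21, adjusted p = 9.39e-06, adjusted p = 0.0998 with an estimated correlation), and the protease gene degP rose by 1.94 ± 0.33. Pyrimidine synthesis was lower (1 of 12 members higher and 5 lower, 2 and 5 adjusted over the list alone, median -0.63, adjusted p = 0.00357, adjusted p = 0.205 with an estimated correlation). Here carB changed by -2.39 ± 0.33 and the uracil permease gene uraA by -2.45 ± 0.43. In all, 376 of 3920 genes changed, 246 higher and 130 lower, 325 by at least 2-fold. The count was 244 without ethanol replicate 3, 230 without control replicate 2, 171 with only the arrays of both groups in the fit and 248 after scaling between arrays. No scan batch held both groups, and scan batch as a block gave 212.

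In 4.5% NaCl, osmotic and stationary-phase genes were among those that rose the most. The periplasmic protein gene osmY rose by 4.62 ± 0.40 (n = 3 and 3), the trehalose synthesis gene otsA by 4.19 ± 0.45, the transketolase gene tktB by 4.21 ± 0.46 and the ribosome-associated protein gene sra by 4.17 ± 0.35. The capsule gene gmd, for colanic acid synthesis, was at least 11.4-fold higher than in the control, where it was not well above background. The porin gene ompF fell (-3.26 ± 0.41), as did the ferric citrate receptor gene fecA (-3.17 ± 0.44), btsT (-2.96 ± 0.44) and the asparagine synthetase gene asnA (-2.17 ± 0.36). The RpoS general stress list rose (27 of 29 members higher, 28 adjusted over the list alone, median 2.87, adjusted p = 3.34e-29, adjusted p = 0.00128 with an estimated correlation). The osmoprotectant list rose (15 of 19 members higher, 15 adjusted over the list alone, median 2.66, adjusted p = 2.52e-14, adjusted p = 0.00898 with an estimated correlation). The glycine betaine transporter gene yehX rose by 3.93 ± 0.33 and the choline transporter gene betT by 3.23 ± 0.32. The outer membrane porin list was lower (5 of 12 members lower, 5 adjusted over the list alone, median -0.68, adjusted p = 0.00357, adjusted p = 0.163 with an estimated correlation). The colanic acid capsule list rose (18 of 20 members higher, 18 adjusted over the list alone, median 2.13, adjusted p = 1.95e-13, adjusted p = 0.0321 with an estimated correlation). The TCA cycle list was higher (13 of 17 members higher, 14 adjusted over the list alone, median 1.21, adjusted p = 6.45e-07, adjusted p = 0.0962 with an estimated correlation). In it acnA rose by 3.51 ± 0.31 and the citrate synthase gene gltA by 2.00 ± 0.27. Pyrimidine synthesis was lower (5 of 12 members lower, 7 adjusted over the list alone, median -0.99, adjusted p = 0.00016, adjusted p = 0.0842 with an estimated correlation), with carB at -2.37 ± 0.33. Flagella and chemotaxis was lower (5 of 48 members lower, 1 adjusted over the list alone, median -0.49, adjusted p = 0.000174, adjusted p = 0.126 with an estimated correlation). Curli and type 1 fimbriae was lower (3 of 14 members lower, 6 adjusted over the list alone, median -0.89, adjusted p = 0.000511, adjusted p = 0.055 with an estimated correlation). In all, 602 of 3934 genes changed, 438 higher and 164 lower, 506 by at least 2-fold. Scaling between arrays gave 321 genes, 267 higher and 54 lower. No scan batch held both groups, and scan batch as a block gave 369.

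In 15% glycerol the maltose genes were among those that rose the most. malP rose by 4.17 ± 0.33, malE by 4.06 ± 0.48, lamB by 4.04 ± 0.42 and the amylomaltase gene malQ by 2.22 ± 0.32 (n = 3 and 3). The glycerol phosphate transporter gene glpT rose by 2.45 ± 0.38, the dipeptide transporter gene dppB by 2.77 ± 0.43 and the alanine exporter gene alaE by 2.43 ± 0.46. The polyamine synthesis gene speD changed by -2.48 ± 0.41, the (p)ppGpp synthetase and hydrolase gene spoT by -2.04 ± 0.37 and the prophage gene yfdI by -3.15 ± 0.64. The glycerol use list was higher (3 of 12 members higher, 6 adjusted over the list alone, median 0.68, adjusted p = 6.23e-06, adjusted p = 0.0151 with an estimated correlation). The facilitator gene glpF had a change of 1.73 ± 0.54, not past the threshold. The osmoprotectant list did not pass (0 of 19 members higher and 1 lower, 2 and 2 adjusted over the list alone, median -0.01, adjusted p = 0.734, adjusted p = 0.935 with an estimated correlation). Its median and test lay below 0, while its mean was above 0 and rounded to 0.00. Its member proP, for a proline and betaine transporter, fell (-1.54 ± 0.25), and proV had a change of 1.42 ± 0.47, not past the threshold. The outer membrane porin list did not pass (1 of 12 members higher and 1 lower, 1 and 2 adjusted over the list alone, median -0.21, adjusted p = 0.523, adjusted p = 0.855 with an estimated correlation), with a mean of 0.01 against a median and test below 0. The maltose system rose (8 of 11 members higher, 8 adjusted over the list alone, median 2.22, adjusted p = 1.3e-14, adjusted p = 0.0024 with an estimated correlation). Pyrimidine synthesis was lower (3 of 12 members lower, 5 adjusted over the list alone, median -0.77, adjusted p = 1.89e-05, adjusted p = 0.0578 with an estimated correlation), with the aspartate carbamoyltransferase gene pyrB at -1.69 ± 0.32. In all, 117 of 3928 genes changed, 75 higher and 42 lower, 106 by at least 2-fold. Scan batch as a block gave 101. The count was 64 without glycerol replicate 2, 55 without glycerol replicate 3, 59 without control replicate 2 and 59 with only the arrays of both groups in the fit, of which 31 were higher and 28 lower.

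NaCl and glycerol, both given as high-solute media, were compared directly. Of 3935 genes, 612 differed, 383 higher in NaCl and 229 higher in glycerol, and 510 by at least 2-fold. osmY was higher in NaCl by 4.53 ± 0.40, tktB by 4.38 ± 0.46, otsA by 4.28 ± 0.45 and poxB by 3.85 ± 0.48 (n = 3 and 3). The maltose genes lamB and malE were lower in NaCl, with differences of -4.53 ± 0.42 and -4.15 ± 0.48, as were malM (-3.06 ± 0.61) and malF (-2.69 ± 0.52), and the transporter gene ycaD (-3.39 ± 0.33). Scan batch as a block gave 600.

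BC at 7 ppm gave no gene past the threshold among 3937 in limma, where 120 had an unadjusted p under 0.05. The Cpx target yebE had a change of 1.13 ± 0.61 (n = 3 and 3), the periplasmic protease gene degP 0.82 ± 0.33 and the efflux genes acrA and acrB 0.78 ± 0.36 and 0.87 ± 0.37, none past the threshold. As a group, the Cpx envelope stress list was higher (0 of 12 members higher, 0 adjusted over the list alone, median 0.46, adjusted p = 0.000277, adjusted p = 0.195 with an estimated correlation, mean change 0.49 and 0.29 without 7 ppm BC replicate 1). The sigmaE envelope stress list did not pass (0 of 17 members higher, 0 adjusted over the list alone, median 0.02, adjusted p = 0.306, adjusted p = 0.719 with an estimated correlation). Multidrug efflux did not pass (0 of 26 members higher, 0 adjusted over the list alone, median 0.10, adjusted p = 0.46, adjusted p = 0.784 with an estimated correlation). Flagella and chemotaxis was lower (0 of 48 members lower, 0 adjusted over the list alone, median -0.31, adjusted p = 9.08e-08, adjusted p = 0.0321 with an estimated correlation). The TCA cycle was lower (0 of 17 members lower, 0 adjusted over the list alone, median -0.37, adjusted p = 7.75e-06, adjusted p = 0.142 with an estimated correlation), and sdhA, for succinate dehydrogenase, had a change of -1.01 ± 0.40, not past the threshold. Anaerobic respiration and fermentation was higher (0 of 58 members higher, 0 adjusted over the list alone, median 0.33, adjusted p = 1.1e-06, adjusted p = 0.58 with an estimated correlation, adjusted p = 0.696 without 7 ppm BC replicate 3), but this list passed in 52.3% of the tests in simulated unchanged groups. Scan batches 4 and 7 held 1 array of each group, and the flagella medians there were -0.25 and -0.13 and the anaerobic medians 0.27 and 0.53.

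BC at 9 ppm gave 5 genes past the threshold among 3929, and 176 with an unadjusted p under 0.05 in limma. ymgD rose by 2.20 ± 0.40, adjusted p = 0.0145, the ribose-binding protein gene rbsB by 1.40 ± 0.26, adjusted p = 0.0145 and the lysozyme inhibitor gene ivy by 1.27 ± 0.26, adjusted p = 0.025 (n = 3 and 3). The gluconate genes gntK and gntT changed by -2.92 ± 0.57, adjusted p = 0.0176 and -2.83 ± 0.55, adjusted p = 0.0176. Each of the 5 genes also passed in another stress, in either direction. In all, ivy was higher in 7 conditions, gntK lower in 7 and gntT lower in 6, against the same control arrays. Scan batch as a block gave 6, and scaling between arrays gave 2, both of them higher. None passed without control replicate 2, control replicate 3 or BC replicate 1, and 1 passed without BC replicate 2. The Cpx list was higher (0 of 12 members higher, 0 adjusted over the list alone, median 0.40, adjusted p = 0.0202, adjusted p = 0.448 with an estimated correlation, adjusted p = 0.192 without control replicate 3, adjusted p = 0.166 after scaling between arrays), and its adjusted p was 0.165 without control replicate 2 and 0.113 without BC replicate 1. The sigmaE list did not pass (0 of 17 members higher, 0 adjusted over the list alone, median 0.08, adjusted p = 0.345, adjusted p = 0.76 with an estimated correlation). Multidrug efflux did not pass (0 of 26 members higher, 0 adjusted over the list alone, median 0.16, adjusted p = 0.305, adjusted p = 0.67 with an estimated correlation), and acrB had a change of 0.87 ± 0.37, not past the threshold. Anaerobic respiration and fermentation was higher (0 of 58 members higher, 5 adjusted over the list alone, median 0.91, adjusted p = 1.82e-27, adjusted p = 0.0998 with an estimated correlation, mean change 0.94 and 0.40 without 9 ppm BC replicate 2). Its medians within scan batches 1, 4 and 7 were 0.34, 2.29 and 0.16. Flagella and chemotaxis was lower (0 of 48 members lower, 0 adjusted over the list alone, median -0.26, adjusted p = 0.000338, adjusted p = 0.142 with an estimated correlation), with medians of -0.24, -0.45 and 0.00 in these batches.

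The doses of BC did not differ in any of 3938 genes in limma, where 57 had an unadjusted p under 0.05. In simulated data for this comparison with 200 changed probes, 89.4% of 4-fold changes and 40.3% of 2-fold changes were recovered. With few changed genes the adjusted threshold is stricter, so these shares overstate what could be found here. Differences of 2-fold or less were mostly not detectable. Only scan batches 4 and 7 held both doses, and scan batch as a block also gave 0.

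EtBr raised the SOS genes of the DNA damage response. umuD, for a subunit of a translesion polymerase, rose by 3.31 ± 0.38 (n = 3 and 3), the repair gene recN by 3.31 ± 0.34, recX by 3.28 ± 0.35, the division inhibitor gene sulA by 3.21 ± 0.41 and dinB by 3.00 ± 0.31. The glutamate dehydrogenase gene gdhA rose by 3.14 ± 0.32. The putrescine importer gene plaP changed by -3.43 ± 0.49, uraA by -3.09 ± 0.43, nmpC by -2.59 ± 0.38 and yghJ by -2.83 ± 0.32. The SOS list rose (18 of 24 members higher, 19 adjusted over the list alone, median 1.87, adjusted p = 2.81e-24, adjusted p = 4.29e-06 with an estimated correlation). Multidrug efflux did not pass (0 of 26 members lower, 0 adjusted over the list alone, median 0.05, adjusted p = 0.85, adjusted p = 0.937 with an estimated correlation). Its median lay above 0, and its mean of -0.01 and its test below 0. The efflux gene mdfA had a change of -1.15 ± 0.43, not past the threshold. DNA supercoiling and nucleoid proteins did not pass (3 of 14 members lower, 3 adjusted over the list alone, median -0.20, adjusted p = 0.0749, adjusted p = 0.652 with an estimated correlation). The topoisomerase I gene topA fell (-2.10 ± 0.36), as did stpA, for a nucleoid protein (-2.07 ± 0.47). Pyrimidine synthesis was lower (2 of 12 members lower, 9 adjusted over the list alone, median -0.92, adjusted p = 1.1e-06, adjusted p = 0.0321 with an estimated correlation). Iron uptake was lower (4 of 34 members lower, 14 adjusted over the list alone, median -0.73, adjusted p = 4.96e-06, adjusted p = 0.238 with an estimated correlation). The RpoS list was higher (4 of 29 members higher, 6 adjusted over the list alone, median 0.40, adjusted p = 0.000721, adjusted p = 0.319 with an estimated correlation, adjusted p = 0.0865 after scaling between arrays), with osmB, for an outer membrane lipoprotein, at 2.77 ± 0.34. In all, 295 of 3935 genes changed, 179 higher and 116 lower, 259 by at least 2-fold. Scan batch as a block gave 424. The count was 116 without EtBr replicate 3, 172 without control replicate 2 and 119 with only the arrays of both groups in the fit.

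At 46 °C the largest rise was in hchA, for the heat-inducible protein Hsp31 (4.51 ± 0.35, n = 3 and 3). alaE rose by 3.51 ± 0.46, the malate synthase gene aceB by 2.97 ± 0.38, the trehalose transporter gene treB by 2.78 ± 0.48 and wrbA by 3.05 ± 0.33. mgtA changed by -2.10 ± 0.34, the RNA helicase gene rhlE by -1.99 ± 0.37, fadL by -1.97 ± 0.28 and the polyamine transporter gene potC by -1.70 ± 0.33. The sigma32 heat shock list was higher (6 of 20 members higher, 8 adjusted over the list alone, median 0.80, adjusted p = 0.00016, adjusted p = 0.328 with an estimated correlation), with the disaggregase gene clpB at 2.44 ± 0.40. The sigmaE envelope stress list did not pass (4 of 17 members higher and 1 lower, 4 and 1 adjusted over the list alone, median 0.21, adjusted p = 0.512, adjusted p = 0.85 with an estimated correlation). Its member degP rose by 1.83 ± 0.33. Ribosomal proteins were lower as a group (0 of 54 members lower, 0 adjusted over the list alone, median -0.11, adjusted p = 0.0316, adjusted p = 0.899 with an estimated correlation, adjusted p = 0.288 without 46 °C replicate 1, adjusted p = 0.162 from the authors' values), with no member past the threshold, but this list passed in 53.8% of the tests in simulated unchanged groups. Without 46 °C replicate 2, control replicate 2 or control replicate 3 the adjusted p was 0.112, 0.0701 and 0.102. The RpoS list was higher (12 of 29 members higher, 14 adjusted over the list alone, median 0.69, adjusted p = 7.53e-09, adjusted p = 0.0694 with an estimated correlation). Acetate metabolism was higher (3 of 9 members higher and 0 lower, 4 and 1 adjusted over the list alone, median 0.69, adjusted p = 0.00794, adjusted p = 0.24 with an estimated correlation), with aceK, for isocitrate dehydrogenase kinase, at 2.52 ± 0.25. Flagella and chemotaxis was lower (2 of 48 members lower, 1 adjusted over the list alone, median -0.25, adjusted p = 0.00193, adjusted p = 0.224 with an estimated correlation). In all, 279 of 3933 genes changed, 203 higher and 76 lower, 247 by at least 2-fold. The count was 136 without 46 °C replicate 2, 154 without control replicate 2, 492 with print-tip loess, 105 after scaling between arrays and 78 with only the arrays of both groups in the fit. No scan batch held both groups, and scan batch as a block gave 131.

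At 15 °C the cold shock genes were among those that rose the most. cspI was at least 58.7-fold higher than in the control, where it was not well above background, cspB rose by 5.14 ± 0.46 and cspG by 3.17 ± 0.48 (n = 3 and 3). The prophage genes ynaE and ynfN were at least 7.22-fold and at least 13.8-fold higher. sra rose by 4.18 ± 0.35, the biofilm-associated gene ymgA by 3.85 ± 0.36, osmY by 3.57 ± 0.40 and the amylase gene amyA by 3.51 ± 0.31. The outer membrane genes nmpC and ompT, for a porin and a protease, changed by -5.06 ± 0.38 and -3.78 ± 0.30, yghJ by -4.87 ± 0.32, borD by -4.38 ± 0.46 and stpA by -4.34 ± 0.47. The cold shock list was higher (6 of 16 members higher, 9 adjusted over the list alone, median 1.06, adjusted p = 0.00016, adjusted p = 0.142 with an estimated correlation). Ribosomal proteins were lower as a group (0 of 54 members lower, 0 adjusted over the list alone, median -0.19, adjusted p = 0.00841, adjusted p = 0.856 with an estimated correlation, adjusted p = 0.403 without 15 °C replicate 1), with no member past the threshold, and the share of 53.8% in simulated unchanged groups applies here too. Fatty acid synthesis did not pass (0 of 15 members lower, 0 adjusted over the list alone, median -0.23, adjusted p = 0.523, adjusted p = 0.892 with an estimated correlation). Its member fabA, for unsaturated fatty acid synthesis, had a change of 0.95 ± 0.36, not past the threshold. The RpoS list rose (23 of 29 members higher and 0 lower, 25 and 1 adjusted over the list alone, median 1.85, adjusted p = 6.82e-15, adjusted p = 0.0184 with an estimated correlation). The osmoprotectant list was higher (10 of 19 members higher and 0 lower, 12 and 1 adjusted over the list alone, median 1.49, adjusted p = 2.7e-05, adjusted p = 0.122 with an estimated correlation). The TCA cycle was higher (13 of 17 members higher, 14 adjusted over the list alone, median 1.35, adjusted p = 1.02e-06, adjusted p = 0.101 with an estimated correlation). Tryptophan synthesis was higher (3 of 7 members higher, 4 adjusted over the list alone, median 0.78, adjusted p = 0.00841, adjusted p = 0.0767 with an estimated correlation), with trpC at 3.27 ± 0.25 and trpA at 2.72 ± 0.33. Pyrimidine synthesis was lower (6 of 12 members lower, 7 adjusted over the list alone, median -1.21, adjusted p = 9.05e-07, adjusted p = 0.0321 with an estimated correlation), with carA and carB at -3.14 ± 0.43 and -3.15 ± 0.33. In all, 768 of 3934 genes changed, 549 higher and 219 lower, 625 by at least 2-fold. Scan batch as a block gave 668. Scaling between arrays gave 360 genes and only the arrays of both groups in the fit gave 478.

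**Figure D2:**
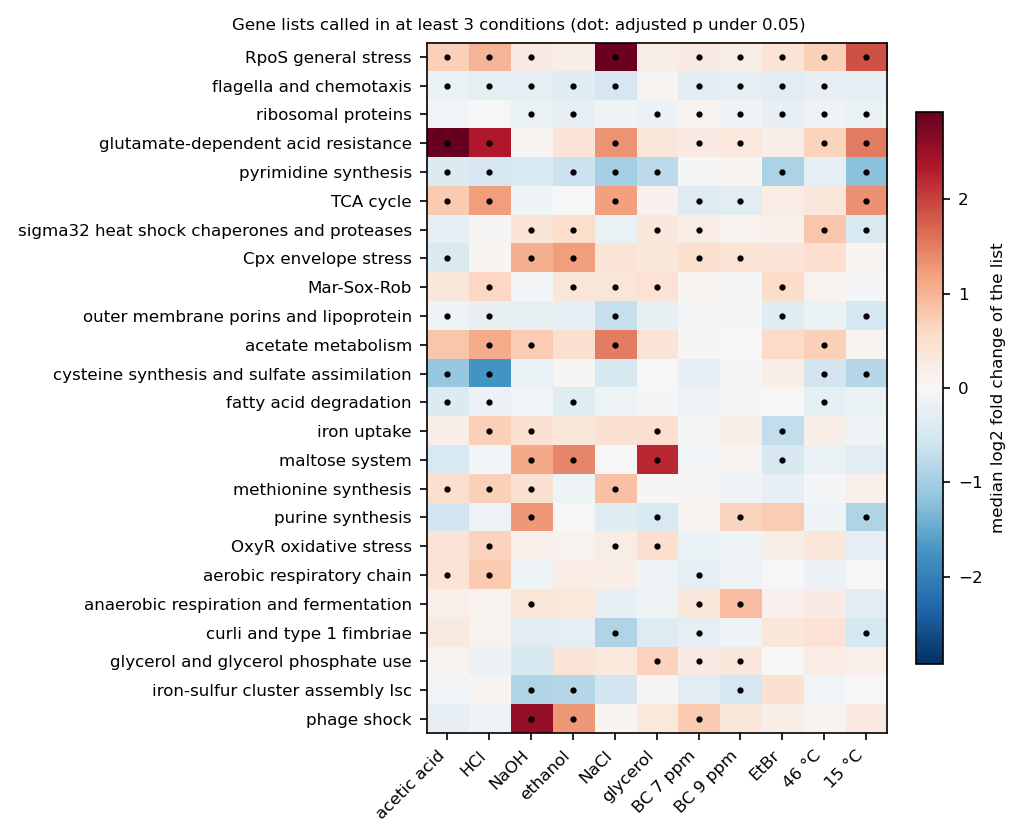
Colour shows the median log2 change of the members of a gene list (24 lists, vertical axis) in each stress against the control (horizontal axis), and a dot marks an adjusted p under 0.05 in the list test. RpoS general stress is dotted as higher in 9 conditions, with a median up to 2.87 in NaCl, and pyrimidine synthesis is dotted as lower in 7 conditions. In all, 131 of 451 tests of a list passed, and 18 of them also passed with an estimated correlation between genes. In 100 simulations of unchanged groups sharing the same control arrays, a mean of 46.3 tests passed and at most 94. The simulated groups were not balanced in replicate number, as the real ones mostly were, so these values may differ for balanced groups. Within that limit, many list calls at the preset correlation can arise without an effect of any stress. By list, the share of simulated tests that passed was 53.8% for ribosomal proteins, 52.3% for anaerobic respiration, 27% for cysteine synthesis, 26.7% for purine synthesis, 23.3% for iron uptake, 22.6% for sigma32 heat shock, 20.6% for glutamate-dependent acid resistance and at most 14.7% for any other.

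Across the 11 conditions, 44 genes changed in the same direction in at least 6, 35 of them higher and 9 lower. alaE, for the alanine exporter, and ghrA, for glyoxylate reductase, were higher in 9 conditions, with mean absolute log2 changes of 1.98 and 1.63 over the 11. The ribosome-associated genes rmf and sra were higher in 8, as were osmB and nlpD, for outer membrane lipoproteins. The aldolase gene fbaB, the iron-sulfur assembly gene sufA, the universal stress gene uspF and hcxB were higher in 7. yghJ and the gluconate kinase gene gntK were lower in 7 conditions. Simulated unchanged groups sharing the same control arrays gave a mean of 0.04 such genes and at most 4 in 100 draws. A mean of only 0.355 genes passed per simulated comparison, so the adjusted threshold was stricter there than in most real comparisons. The simulations therefore cannot tell how many of the 44 come from the shared controls. The 3 control arrays are too few to divide, so part of the excess may come from the shared controls. The count was 15 without control replicate 2, 27 without control replicate 1, 63 without control replicate 3 and 28 without HCl replicate 3, of which 13, 22, 35 and 28 were among the 44, and scaling between arrays gave 18.

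In total, 686 genes were past the threshold against the control in 1 condition only and also differed in the same direction from the mean of the other stresses. Growth at 15 °C had 272 of them, led by cspI, cspB, ynfN and cspG. NaCl had 136, led by gmd, yciF, wza and ydeI, and EtBr had 89, led by recN, sulA, dinB and yebG. Ethanol had 70, led by spy, norV, cyoA and cyoB, 46 °C had 46 and NaOH 27, where thiC, thiE, thiG and thiH led. Glycerol had 24, led by waaL, for O-antigen ligase, acetic acid 16, led by appC, for a cytochrome bd-II oxidase subunit, and HCl 6, led by yeaR. Neither BC dose had any. A gene of this kind can still lie above the control in another stress without passing there, as appC does in HCl (1.68 ± 0.54, adjusted p = 0.0826). Its call can also rest on 1 measured array of a group, as for yibH at 46 °C. With 1 array left out, the lowest or highest counts more than 1.5 times away from these were as follows. EtBr had 32 without EtBr replicate 3, 46 °C had 12 without replicate 2, glycerol had 6 without replicate 3 and HCl had 0 without replicate 3. The others were 13 and 54 for NaOH without replicates 1 and 3, 38 for ethanol without replicate 3, 9 and 30 for acetic acid without its replicate 2 and without HCl replicate 3, and 77 for NaCl without replicate 3.

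**Figure D3:**
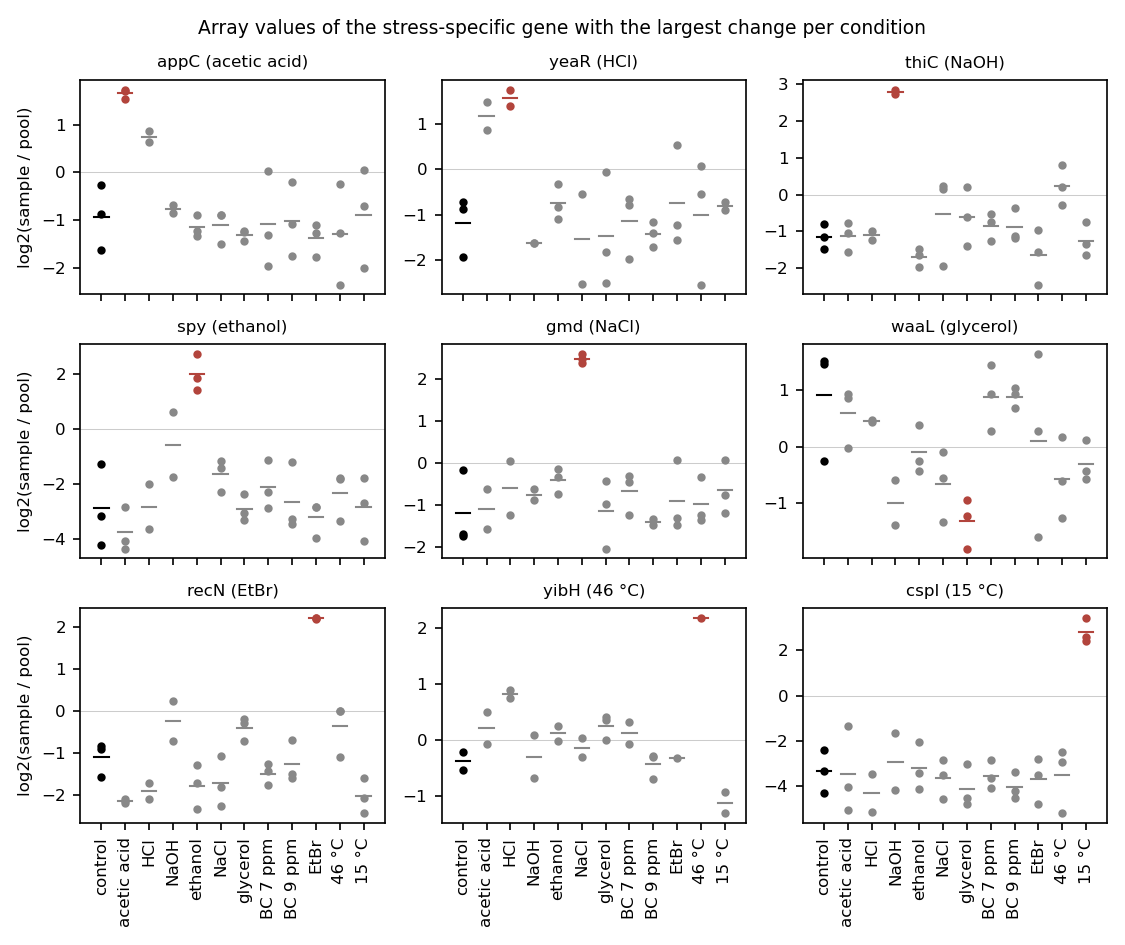
Each panel shows 1 gene, the stress-specific gene with the largest change in 1 of 9 conditions, with the normalized log2 ratio of sample to pooled reference on the vertical axis and the 12 groups on the horizontal axis. Points are arrays, bars are group means, red is the named condition and black the control. yibH, the gene shown for 46 °C, has 1 measured array there, so its call rests on that array with a spread taken from the other groups.

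The 55 pairs of stresses were compared by the covariance of their log2 changes over 3899 genes, which are not independent replicates. The median correlation was 0.40, from 0.14 to 0.81, against a mean of 0.48 for simulated unchanged groups, since shared control arrays alone give a correlation. The median covariance was 0.155 against 0.0688 simulated, and 31 pairs lay above the 95th percentile of the simulations. NaCl and 15 °C had the largest covariance, at 0.434, and 253 genes higher in both where independent lists would share 61.2. Acetic acid and HCl had the highest correlation, at 0.81, with a covariance of 0.315 and 81 genes higher in both where independent lists would share 4.7. BC at 9 ppm and 15 °C had the smallest covariance relative to the simulations. Part of each excess may come from the shared controls, as the simulation leaves out the effects and the independent lists leave out the shared arrays.

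**Figure D4:**
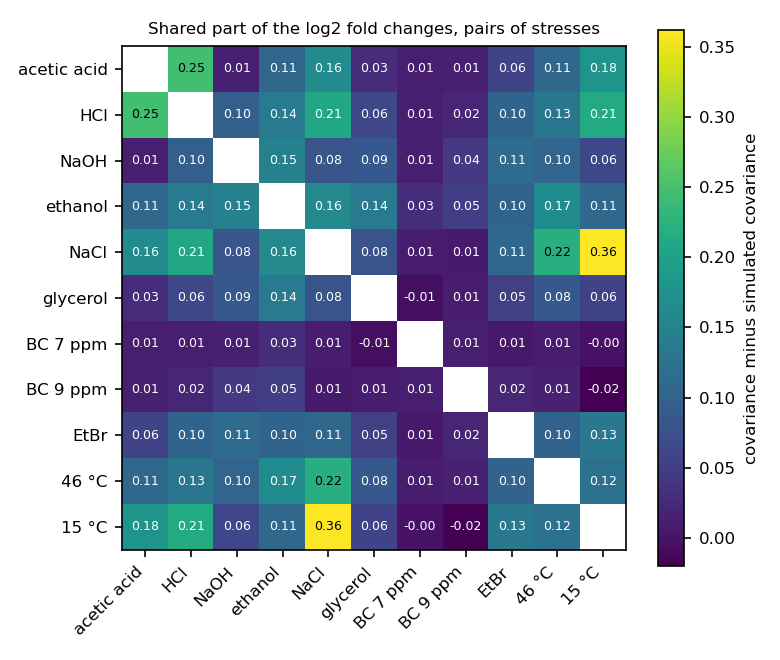
Each cell shows, for a pair of stresses, the covariance of log2 changes across genes minus the mean covariance of simulated unchanged groups that share the control arrays, in squared log2 units. NaCl with 15 °C has the highest value (0.36), and the pairs with BC lie between -0.02 and 0.05.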

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

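Of the tests below, the simulated groups, the members of the RpoS list, leaving out 1 BC array and the tests on the flagella list alone were chosen only after the result was seen.

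NaCl and glycerol moved 4 genes in opposite directions against the control. bax, for a peptidoglycan hydrolase, was higher in NaCl than in glycerol by 3.43, spoT, for (p)ppGpp turnover, by 3.4, and the osmolyte transporter gene proP by 2.98. The transporter gene ycaD was lower in NaCl, with a difference of -3.39. Genes past the threshold in opposite directions against the control were most frequent for ethanol and 15 °C (29), where btsT rose by 1.58 in ethanol and changed by -3.11 in the cold. They numbered 15 for ethanol and NaCl, 14 for 46 °C and 15 °C, and 13 for ethanol and EtBr. Among the 14, ytfT had a standard error of 0.44 at 46 °C and 0.31 at 15 °C, since fewer arrays gave a value at 46 °C. The genes in these counts were chosen by their opposite calls, so a test of the difference would add nothing.

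Probes that matched no gene of MG1655 lie outside the comparisons of the report, and some of them passed the same threshold. Their number was 8 in acetic acid (2 lower), 19 in HCl (11 lower), 8 in NaOH (3 lower), 32 in ethanol (17 lower) and 72 in NaCl (49 lower). It was 7 in glycerol (5 lower), 2 in BC at 9 ppm (1 lower), 35 in EtBr (25 lower), 23 at 46 °C (17 lower) and 132 at 15 °C (102 lower). Between NaCl and glycerol it was 50 (34 lower in NaCl). Causes were tested at 15 °C only.

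At 15 °C, 77.3% of the called probes without a matching gene were lower, against 28.5% of the called K-12 genes. Dim probes were tested as the cause with K-12 probes of matched brightness, of which 18.3% of the calls were lower, which argues against it. Without background correction 79.4% of the calls among the probes without a match were lower, which argues against background correction as the cause. Cross-hybridization of other transcripts was not tested, and no biological explanation was tested.

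The 44 genes that changed the same way in at least 6 stresses were weighed against technical causes. Chance values of the shared control arrays alone gave at most 4 genes in the simulations. Few genes passed there, which makes the adjusted threshold stricter, so this does not bound their number among the 44. For 1 outlying control array, all 3 control arrays lay beyond the median of the stress arrays in 44 of the 44 genes, but the genes were chosen with these control arrays, so this excludes nothing. Without control replicate 2 only 15 genes were shared, 13 of them among the 44, and 27 without control replicate 1, 22 of them among the 44, while 63 were shared without control replicate 3, 35 of them among the 44, so an outlying control array stays open. Among the 35 genes higher in at least 6 stresses, 3 were members of the RpoS list where 0.257 are expected (Fisher's exact p = 0.00199). This p is descriptive only, since genes that share control arrays are not independent and the list was already called higher in 9 conditions. Of the 35 genes 91.4% lie outside the list, but it holds only 29 of the 3952 genes tested. That share therefore does not tell how much of the shared response depends on RpoS. An error shared by all 3 control arrays stays open, since no other control was measured.

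With BC, the anaerobic respiration list was higher and the flagella list lower at both doses at the preset correlation. With an estimated correlation the adjusted p was 0.58 at 7 ppm and 0.0998 at 9 ppm for the anaerobic list, and 0.0321 and 0.142 for the flagella list. In simulated unchanged groups the anaerobic list passed in 52.3% of the tests and the flagella list in 6.27%. For scan batch as the cause, 9 of 10 list medians within a scan batch had the direction of the pooled value. At 9 ppm each array had a control array in its scan batch, so the pooled change is built from these pairs. The direction within batches was therefore largely fixed and excludes nothing. A shift common to both arrays of a batch cancels from the pooled 9 ppm change of genes with a value on every array. A batch effect that differs between these arrays stays open. The sizes differed between batches, with anaerobic medians of 0.34, 2.29 and 0.16 at 9 ppm in batches 1, 4 and 7. For 1 control array as the cause, 12 of 12 list calls were kept without 1 control array, but calls of the anaerobic list are too frequent in unchanged groups for this to exclude it there. For the flagella list alone, 6 of 6 calls were kept without 1 control array at the preset correlation, which argues against that cause for this list. With scan batch as a block its highest adjusted p over both doses was 0.000242 in limma camera. At 9 ppm the block adds little, since BC and control arrays fill the same scan batches and a shift common to a batch already cancels. At 7 ppm only 2 scan batches held both groups, and the call held. This argues against a shift common to a batch as the only cause at that dose. The flagella medians within those batches were smaller in size than the pooled one, so part of it may rest on arrays without a partner. For 1 BC array as the cause at 7 ppm, the adjusted p of the anaerobic list rose to 0.696 without replicate 3, as that explanation needs. At 9 ppm the highest such value was 2.83e-05, but the mean change went from 0.94 to 0.40 without replicate 2, so 1 BC array stays open there too. Correlation between the genes of the anaerobic list stays open as a cause at both doses, and so does an effect of BC.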

How the results depend on the processing

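The count of genes past the threshold stayed within 1.5 times the value in the report for every comparison without background correction, with the signal median, without the filter on dim probes, with the authors' values and with the replicate number as a block. As a replicate block, the number gave 223 genes in acetic acid, 210 in HCl, 134 in NaOH, 446 in ethanol, 698 in NaCl, 154 in glycerol, 0 and 6 in BC, 359 in EtBr, 379 at 46 °C, 871 at 15 °C and 133 lists; it ended 1 list call, in glycerol, and gained 3, and of 596 values of named genes it ended 2 calls and gained 12. Leaving out both arrays of scan batch 1, leaving out arrays for the shared genes, the lists and the similarity, and scan batch as a block for the lists were chosen after seeing the data. Without background correction the sign turned for alaE in 9 ppm BC (-0.0258) and hcxB in 9 ppm BC (-0.13). With print-tip loess the number of genes was 492 at 46 °C and 1 for 9 ppm BC against 7 ppm BC. With print-tip loess the sign turned for yghJ at 46 °C (-0.0706). After scaling between arrays the number of genes was 116 in acetic acid, 250 in NaOH, 248 in ethanol, 321 in NaCl, 2 in 9 ppm BC, 105 at 46 °C, 360 at 15 °C and 1 for 9 ppm BC against 7 ppm BC. After scaling between arrays 18 genes were shared by at least 6 stresses. After scaling between arrays the sign turned for gntK in 7 ppm BC (0.14), fbaB in 7 ppm BC (-0.11), hcxB in 7 ppm BC (-0.22), alaE in 9 ppm BC (-0.23), ghrA in 9 ppm BC (-0.0208), sufA in 9 ppm BC (-0.0106), hcxB in 9 ppm BC (-0.18), yghJ at 46 °C (-0.0759), the RpoS general stress list in NaOH (-0.20), the RpoS general stress list in 7 ppm BC (-0.0682) and the RpoS general stress list in 9 ppm BC (-0.0173). With flagged spots kept the number of genes was 1 for 9 ppm BC against 7 ppm BC. With only the arrays of the groups compared the number of genes was 103 in HCl, 25 in NaOH, 171 in ethanol, 59 in glycerol, 3 in 9 ppm BC, 119 in EtBr, 78 at 46 °C, 478 at 15 °C and 2 for 9 ppm BC against 7 ppm BC. With scan batch as a block the number of genes was 96 in acetic acid, 212 in ethanol, 369 in NaCl and 131 at 46 °C. With scan batch as a block the sign turned for alaE in 7 ppm BC (-0.13), rpsU at 46 °C (0.0129) and the purine synthesis list in HCl (0.74). Of these only the purine list passed in the new direction, with an adjusted p of 0.0495 in limma camera. With an estimated correlation 18 of 131 lists passed. Without both arrays of scan batch 1 the number of genes was 0 in 9 ppm BC. Without both arrays of scan batch 1 the sign turned for sufA in 9 ppm BC (-0.0635). With 1 array left out the lowest and highest counts were 15 to 63 for the genes shared by at least 6 stresses, 55 to 108 in glycerol, 56 to 163 in HCl, 1 to 3 for acetic acid against HCl, 42 to 179 in NaOH, 99 to 215 in acetic acid, 136 to 330 at 46 °C, 230 to 400 in ethanol, 0 to 4 in 9 ppm BC and 116 to 301 in EtBr. The sign turned for values that ran, with 1 array left out, from -0.61 to 0.0293 for the ribosomal proteins list in NaOH, -0.0405 to 1.04 for the anaerobic respiration and fermentation list in NaOH, -2.10 to 0.16 for rpsT in NaOH, -1.79 to 0.049 for rpsO in NaOH, -0.61 to 0.0127 for atpF in NaOH, -0.0414 to 3.87 for nirB in NaOH, -0.0399 to 0.24 for yghJ at 46 °C and -0.94 to 0.10 for rpsT at 15 °C. The others ran from -0.0525 to 0.73 for rseA in 7 ppm BC, -0.20 to 0.91 for alaE in 7 ppm BC, -0.59 to 0.0198 for gntK in 7 ppm BC, -0.26 to 0.39 for hcxB in 7 ppm BC, -0.51 to 0.61 for alaE in 9 ppm BC, -0.0483 to 0.55 for ghrA in 9 ppm BC, -0.0266 to 0.44 for sufA in 9 ppm BC and -0.29 to 0.43 for hcxB in 9 ppm BC. Of 401 calls of named genes, 131 ended when at least 1 array was left out, and of the 131 list calls 50 did. With only the groups compared, fewer arrays gave the spread, and it was no longer shared with the other groups. Between stresses that setting gave 604 genes against 612 for NaCl and glycerol and 4 against 3 for the acids. Fewer arrays alone therefore need not lower the count. With 1 array left out a group has fewer arrays, and a lone array is assumed to vary like the other groups. Why the counts moved was not tested for any setting. Between 51.4% and 89.9% of matched probes were well above background on an array, which limits what dim genes can show.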

Other observations

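The simulated list calls and the tests on other splits of the arrays were chosen only after the results were seen.

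The 11 comparisons share the 3 control arrays, so each tally of list calls stands beside 100 simulations of unchanged groups that share them. Flagella and chemotaxis was lower in 9 conditions and higher in 0, and the simulations gave at most 6 in the same direction. Pyrimidine synthesis was lower in 7 (at most 5), outer membrane porins in 5 (at most 4) and fatty acid degradation in 4 (at most 3). With an estimated correlation 1 of the 9 flagella calls and 2 of the 7 pyrimidine calls were kept, and none for the porins or fatty acid degradation. Ribosomal proteins were lower in 7 and higher in 1, but 27 of the simulations gave as many in 1 direction, and cysteine synthesis and sulfate assimilation was lower in 4, which 28 of them reached.

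RpoS general stress was higher in 9 conditions, which 1 of the simulations reached, glutamate-dependent acid resistance in 7, which 5 reached, and the Mar-Sox-Rob list in 5, which none reached. With an estimated correlation 3, 2 and 0 of these calls were kept. After scaling between arrays the mean change of the RpoS list turned to -0.20 in NaOH, -0.0682 in BC at 7 ppm and -0.0173 in BC at 9 ppm. Sigma32 heat shock was higher in 5 conditions and lower in 1, and 17 of the simulations gave as many. Of all 131 list calls, 18 were kept with an estimated correlation.

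Leaving out 1 control array moved the similarity between stresses. The median correlation was 0.43 without control replicate 1, 0.42 without replicate 2 and 0.53 without replicate 3, against 0.40 with all control arrays. With fewer shared control arrays their chance values weigh more in every change, which can raise the correlation by itself. No simulation was run with 1 control array left out, so the rises cannot be assigned to single arrays.

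Groups of 3 arrays against 3 can be split in 10 ways, too few for a share under 0.05. The other splits mix arrays of both groups, so any effect of the stress adds to the spread within their sides. Their low counts are therefore not those of unchanged groups, and the gap to the real count decides nothing. The real count and the highest other were 175 and 4 in acetic acid, 376 and 1 in ethanol, 602 and 2 in NaCl, 117 and 0 in glycerol, 0 and 0 in BC at 7 ppm, 295 and 2 in EtBr, 279 and 2 at 46 °C, 768 and 0 at 15 °C, 0 and 1 between the BC doses, and 612 and 1 between NaCl and glycerol. In BC at 9 ppm, 2 of the 10 splits gave at least as many genes as the real 5, the real one included. The other one gave 16 and set replicate numbers 2, 3 and 3 against 1, 1 and 2, so it differs in replicate number as well. Of the 4 splits with all 3 replicate numbers on both sides, the real one gave 5 and the other 3 gave 0, and with replicate number as a block the comparison gave 6. The real split alone gave its count in 8 of the 11 comparisons, and in BC at 7 ppm and between the doses all 10 splits gave at least the real 0.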
